A study of Homo sapiens with 6 samples.

How the data were processed

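PTBP1 RIP-seq was analysed in 3 DCRT-KO and 3 WT libraries of AC16 cells. The labels name AC16 as the cell line, while their growth protocol describes the cells in terms of a commercial supplier; whether they are the established line of that name was not checked here. Per the labels' protocols, RNA was extracted with a phenol-based reagent, libraries were made with a strand-specific kit and sequenced as paired ends on an Illumina HiSeq. Per the submitters' processing notes, cutadapt 1.2.1 was among the tools used. The aligner, the counting tool and the genome build are not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

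The authors deposited 1 table of FPKM (fragments scaled to gene length and library total) with 20024 genes, their identifiers, names, positions and lengths. Of the identifiers, 19981 were found in GENCODE 29 and 19939 were protein-coding there. The positions in the file overlapped those of GENCODE 29 (GRCh38) on the same chromosome for 19934 genes and had the same start and end for 12704; positions are printed as the deposited file gives them. FPKM fixes each library's total, so a rise in some genes lowers all others, and it removes depth. FPKM times length was a whole multiple of 1 step per column in 100% of values (tolerance 1e-06), which gave the reads behind each value. Totals ran from 373354 to 2589080 reads, and 3 reads, the floor used for genes with none, correspond to 1.16 RPM (reads scaled to the library total) in the deepest library and 8.04 in the shallowest. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

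DCRT-KO columns were matched to samples by name. The WT columns repeat a replicate number and were matched to the group only. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 2.82 to 5.88), so all 6 were kept as separate libraries. The number of per-sample FPKM columns left unused was 0.

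Genes with a mean of at least 1 FPKM (11445 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are DCRT-KO minus WT on that scale, which understates the change of low genes. FPKM values are means ± SD and log2 differences carry their SE. Gene lists were tested with camera with a preset correlation of 0.01 and the same variance trend, adjusted over the 21 lists with at least 3 tested genes. Of 24 lists fixed before the data were examined, the blood and immune markers had no tested gene, and the long and small noncoding RNA lists were not analysed here. Shares of library totals were compared by exact permutation. Transcript shares within genes were not analysed, because each row of the table is a gene.

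The rule for named genes, also fixed before the data were examined, took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher mean was at least 2 FPKM; PTBP1, PTBP2, PTBP3 and any row for DCRT; and from each list up to 4 members past the threshold with the smallest adjusted p, or the 2 with the highest mean when none passed. Some genes that this rule takes are not reported here. Ratios of means use FPKM. Folds for genes with no read in a group use pooled RPM and 3 reads over that group.

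The test was run on 10 simulated sets with the real means, depths and genes (11445) and 200 changed genes. Every gene and library had the same spread between replicates (negative binomial dispersion 0.0125), and no library was set apart as DCRT-KO replicate 3 is. The rates below hold for that setting and need not hold for the real libraries. For DCRT-KO against WT, limma recovered 39.7% of 2-fold and 84.7% of 4-fold changes with on average 6 false calls among 130.4, and voom 64.7% and 90.9% with 6.9 false calls. With no changed gene, limma made at most 2 calls.

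Settings varied, as chosen before the data were examined, were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, limma without a variance trend or with robust estimation, a minimum log2 difference, each library left out, camera with an estimated correlation, and fry. Settings added after the data were seen were voom on the whole reads, with and without sample quality weights, all libraries thinned to 373354 reads (20 draws), both shallowest libraries left out, and removal of each library's trend with GC content and transcript length, taken from GENCODE 29 transcripts. Gene counts and correlations in thinned libraries use all 20 draws. Values of named genes, lists and genome windows use the first draw only, so their spread over draws is not known. Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3 were used to prepare the table.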

Results

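The series measured RNA recovered with the RNA-binding protein PTBP1 from AC16 cells, a line that the labels describe as human cardiomyocytes. In RNA immunoprecipitation followed by sequencing (RIP-seq), an antibody pulls down a protein together with the RNA bound to it, and that RNA is sequenced. PTBP1, the polypyrimidine tract-binding protein, binds CU-rich stretches of transcripts and controls splicing, stability and translation. There were 3 libraries from cells in which the long noncoding RNA DCRT had been knocked out (DCRT-KO) and 3 from wild-type (WT) cells, all with the PTBP1 antibody. The comparison asks which transcripts differ in PTBP1 RIP when DCRT is missing, a question that the series title places in dilated cardiomyopathy. Libraries of input RNA or of a control antibody were not analysed here. A difference in RIP level can therefore reflect transcript abundance, PTBP1 binding or background RNA carried along unbound. The WT columns carry no usable replicate numbers and are called WT library a, b and c in column order.

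Whole reads worked back from the FPKM values totalled 2589080, 1798841 and 2062766 in WT libraries a, b and c, and 528371, 373354 and 1380722 in DCRT-KO libraries 1, 2 and 3. Every DCRT-KO library was thus shallower than every WT library, so depth goes with genotype here. Between 12074 and 14382 of the 20024 listed genes had at least 1 read. No listed gene carried the name DCRT, so the knockout itself was not checked here. PTBP1 mRNA, whose product was the target of the antibody, had 119 ± 17.2 FPKM in DCRT-KO and 118 ± 11.7 in WT RIP (mean ± SD, n = 3 each; log2 difference 0.01 ± 0.17 SE, limma adjusted p = 0.977).

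The fast muscle myosin heavy chains MYH13 and MYH4 had no read in any WT library and reads in every DCRT-KO library. CXCL8, the neutrophil-attracting chemokine interleukin 8, fell from 74.1 ± 7.71 FPKM in WT to 3.59 ± 4.46 in DCRT-KO RIP, where libraries 1, 2 and 3 had 0.845, 1.196 and 8.73 FPKM. Of 11445 genes tested with limma on log2(FPKM + 1), 269 were higher and 137 lower in DCRT-KO at an adjusted p below 0.05. In all 406 of them the DCRT-KO and WT values did not overlap. Among all tested genes the values of the 2 groups did not overlap in 30.3%, against 10% by chance. Quantile normalization changed the split to 281 higher and 278 lower genes.

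Among the 10 largest rises, MYH13 reached 10.2 ± 2.80 FPKM in DCRT-KO (24, 23 and 110 reads in libraries 1, 2 and 3; log2 difference 3.45 ± 0.29 SE, adjusted p = 0.00485) and MYH4 6.67 ± 1.17 FPKM (17, 17 and 59 reads; 2.93 ± 0.28, adjusted p = 0.0056). Set against a floor of 3 reads over the WT group, MYH13 was at least 148-fold and MYH4 at least 87.6-fold higher in pooled RPM. Without DCRT-KO replicate 3 these bounds were 112-fold and 81.1-fold, and bounds without a WT library were not worked out. Both genes lie in a cluster on chromosome 17, MYH13 at 10300865 to 10373130 and MYH4 at 10443290 to 10469559. MYH8, MYH1 and MYH2, which were singled out after their values were seen, had 0 reads in WT and 28, 64 and 51 in the DCRT-KO libraries together. The absence in WT did not cover the whole cluster. Its embryonic myosin MYH3, next to MYH2, had 9.61 pooled RPM in WT and 14.02 in DCRT-KO (62 and 32 reads). Beyond it SCO1, a cytochrome c oxidase assembly factor, had 82.9 and 85.9 (535 and 196 reads). The myosins of the cluster are close paralogs, so how the reads divide among them is uncertain.

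**Figure D1:**
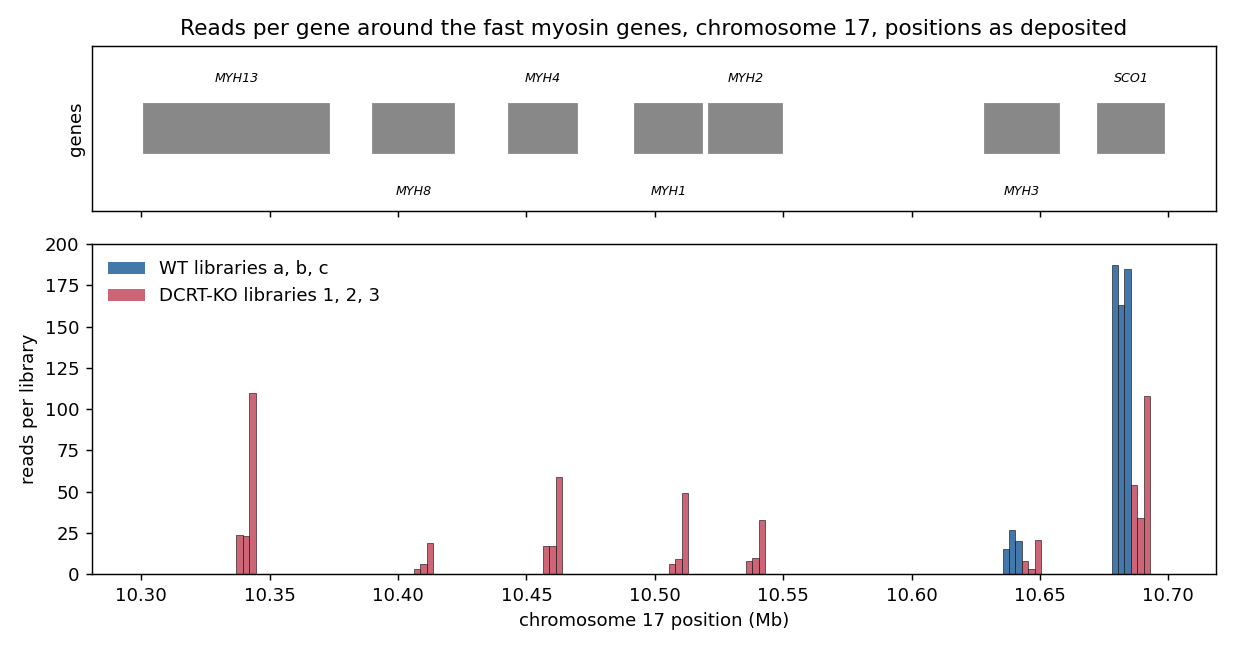
Reads per library (lower panel, linear axis) for genes between MYH13 and SCO1 on chromosome 17, drawn at the middle of each gene, with gene extents as boxes in the upper panel. The blue WT bars are absent (0 reads) over MYH13, MYH8, MYH4, MYH1 and MYH2, where all 3 DCRT-KO libraries in red have reads, and both groups have reads over MYH3 and SCO1.

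Whether the other large rises share a function was not tested. CLCF1, a cytokine of the interleukin 6 family, rose from 2.16 ± 0.494 to 16.0 ± 3.68 FPKM (log2 difference 2.41 ± 0.25 SE, adjusted p = 0.00699). PCOLCE, an enhancer of procollagen processing, rose from 0.537 ± 0.258 to 6.80 ± 1.88 FPKM (adjusted p = 0.0102), and PKP3, a desmosomal plaque protein, from 2.15 ± 0.592 to 15.2 ± 7.48 (adjusted p = 0.023). IL1RAPL2, of the interleukin 1 receptor family, rose from 0.676 ± 0.20 to 10.8 ± 4.75 FPKM, and the homeobox gene ESX1 from 4.67 ± 3.19 to 26.9 ± 9.35. Both lie near each other on chromosome X, ESX1 at 104250038 to 104254933 and IL1RAPL2 at 104566315 to 105767829. PLTP, the phospholipid transfer protein, HIST1H3C, a histone H3 gene, and UFC1, the E2 enzyme of the UFM1 pathway, also rose, with adjusted p of 0.0269, 0.0398 and 0.0363. Many of these genes rest on few reads. PCOLCE had 3, 5 and 3 reads in WT and 9, 11 and 30 in DCRT-KO, and IL1RAPL2 7, 4 and 3 against 27, 10 and 33. PLTP had 5, 0 and 3 reads in WT and 4, 10 and 27 in DCRT-KO. HIST1H3C had 2, 0 and 4 against 3, 3 and 6, and UFC1 1, 0 and 0 against 8, 6 and 4.

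CXCL8 had the largest fall by the rule for named genes. It fell by 4.46 ± 0.53 SE on the log2(FPKM + 1) scale (adjusted p = 0.00848), with 382, 303 and 375 reads in WT and 1, 1 and 27 in DCRT-KO libraries 1, 2 and 3. CXCL1, a chemokine of the same family, fell from 14.8 ± 7.32 to 2.48 ± 1.28 FPKM (adjusted p = 0.0255; 0.0573 with voom on whole reads). BIRC3, an inhibitor of apoptosis and ubiquitin ligase, fell from 4.61 ± 0.199 to 0.341 ± 0.393 FPKM (adjusted p = 0.0176), with 1, 0 and 8 reads in DCRT-KO libraries 1, 2 and 3 and a DCRT-KO mean of 0.126 FPKM without library 3.

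ZNF850, a zinc finger gene, and STOM, the membrane protein stomatin, had 86, 60 and 84 and 32, 26 and 33 reads in WT and none in any DCRT-KO library. Against a floor of 3 reads over the DCRT-KO group, they were at least 27.1-fold and 10.7-fold lower in pooled RPM, both with an adjusted p of 0.00848. Without DCRT-KO replicate 3, which holds most of the DCRT-KO reads, these bounds were 10.72-fold and 4.24-fold. The receptor gene GPRC5D, with 13, 10 and 16 reads in WT and none in DCRT-KO, was at least 4.6-fold lower by the same floor, or 1.82-fold without DCRT-KO replicate 3 (adjusted p = 0.00829). TAS2R19, a bitter taste receptor, had 16, 15 and 16 reads in WT and 0, 0 and 2 in DCRT-KO. C9orf92, DEFB135 and the keratin-associated KRTAP4-9 also passed the limma test but lay near the floor, DEFB135 with 5, 1 and 1 reads in WT and none in DCRT-KO. None of these 3 genes or TAS2R19 passed when whole reads were tested with voom (adjusted p = 0.268, 0.761, 0.181 and 0.0827). Of the 48 named genes past the threshold, 41 passed with voom; the others not passing were CXCL1, HIST1H3C (0.0514) and NDUFS5 (0.125).

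**Figure D2:**
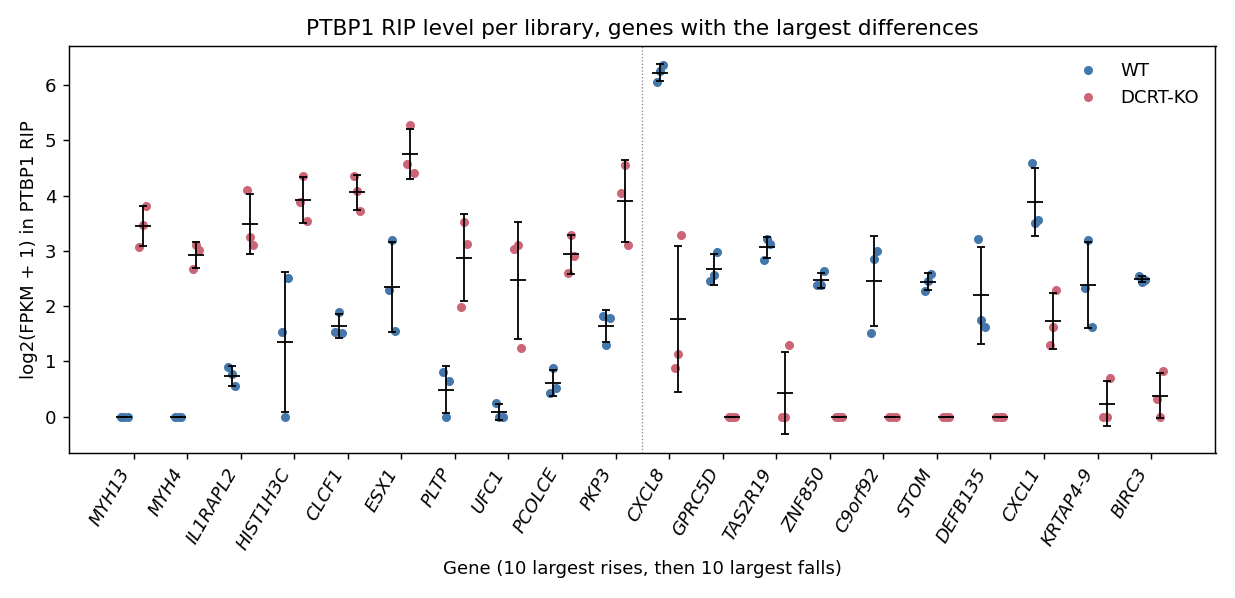
PTBP1 RIP level, as log2(FPKM + 1), of the 10 genes with the largest rises and the 10 with the largest falls, with 1 point per library (WT blue, DCRT-KO red), a bar at the group mean and whiskers of 1 SD (n = 3). For each of these genes the 3 DCRT-KO points lie on one side of the 3 WT points, and MYH13 and MYH4 in WT and GPRC5D, ZNF850, C9orf92, STOM and DEFB135 in DCRT-KO lie at 0.

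The PTBP1 paralogs were also fixed beforehand. PTBP3 had 43.3 ± 1.31 FPKM in WT and 23.7 ± 7.82 in DCRT-KO (log2 difference -0.88 ± 0.22 SE, adjusted p = 0.0588; 0.0106 with voom). PTBP2, the neuronal paralog, had 11.04 ± 1.83 FPKM in WT and 7.92 ± 0.406 in DCRT-KO, which did not pass (adjusted p = 0.238).

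Of 77 cytosolic ribosomal protein genes tested, 68 had higher values in DCRT-KO, 10 rose and none fell past the threshold, and 36 rose and 2 fell when adjusted over the list alone. Their median log2 difference was 0.50 (limma camera adjusted p = 2.04e-13), a call lost with an estimated correlation (adjusted p = 0.697). RPS27A rose from 35.2 ± 8.60 to 88.7 ± 17.3 FPKM (adjusted p = 0.0235), RPL11 from 70.8 ± 4.99 to 145 ± 28.7 and RPS21 from 80.2 ± 16.0 to 172 ± 31.4. The list of mostly replication-dependent histone genes, which package newly copied DNA, had a median log2 difference of 0.88 over 19 genes, of which 18 were higher (camera adjusted p = 1.71e-07; adjusted p = 0.697 with an estimated correlation). Its only lower gene was H1FX, a linker histone that is not replication-dependent and was singled out after its values were seen (log2 difference -1.53, adjusted p = 0.27). HIST1H3H, HIST1H2AG and HIST1H4C rose past the threshold and none fell, against 13 and 0 adjusted over the list alone; HIST1H3H went from 33.4 ± 4.92 to 138 ± 37.3 FPKM (adjusted p = 0.00829). HIST1H4C, HIST1H2AG and HIST1H3H all lie on chromosome 6, between 26103876 and 27811300. In the 10 Mb window that holds them, 56 of 85 genes were higher, with a median log2 difference of 0.52. Whether their rise is separate from that of their neighbours was not tested.

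Glycolysis genes had a median log2 difference of 0.55, with 19 of 22 higher in DCRT-KO (camera adjusted p = 2.28e-06; adjusted p = 0.697 with an estimated correlation). The kinases PFKFB4, PFKP, PFKL and HK1 and the glucose transporter SLC2A1 rose and none fell, against 10 and 0 adjusted over the list alone. SLC2A1 rose from 49.3 ± 6.39 to 96.4 ± 6.71 FPKM (adjusted p = 0.0238), PFKFB4 from 4.90 ± 1.57 to 17.4 ± 4.25 (adjusted p = 0.0231) and HK1 from 18.3 ± 0.533 to 39.4 ± 9.0 (adjusted p = 0.0269). PKM, the pyruvate kinase whose splicing PTBP1 controls, had a log2 difference of 0.09 (adjusted p = 0.801). The fry test gave an adjusted p of 0.14 for each of the ribosomal protein, histone and glycolysis lists.

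Nuclear-encoded subunits of respiratory complexes II to V were higher in 28 of 36 genes, with a median log2 difference of 0.20 (camera adjusted p = 0.00775; adjusted p = 0.697 with an estimated correlation; 0.167 without DCRT-KO replicate 3). ATP5F1D of ATP synthase, UQCRC1 of complex III and COX6B1 of cytochrome c oxidase rose and none fell, against 4 and 0 adjusted over the list alone. UQCRC1 went from 16.9 ± 3.87 to 58.8 ± 19.4 FPKM (adjusted p = 0.0175). Of 34 complex I genes, NDUFB7, NDUFS5 and NDUFS8 rose and none fell (5 and 0 adjusted over the list alone), with 17 higher and 17 lower in all (camera adjusted p = 0.319). NDUFB7 rose from 35.5 ± 10.9 to 129 ± 40.2 FPKM (adjusted p = 0.0231). None of the 13 mitochondrially encoded mRNAs passed, also when adjusted over the list alone; their median log2 difference was -0.31 (camera adjusted p = 0.319, and 0.00332 without DCRT-KO replicate 1). MT-CO1 had 31069 ± 3138 FPKM in WT and 25639 ± 7694 in DCRT-KO.

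FIS1, which acts in mitochondrial fission, and the metabolic regulator ESRRA rose among 20 genes of mitochondrial dynamics, mitophagy and biogenesis (2 also adjusted over the list alone; camera adjusted p = 0.672). ACADVL, the very long chain acyl-CoA dehydrogenase, rose among 19 fatty acid oxidation genes (2 adjusted over the list alone) from 17.05 ± 4.52 to 37.5 ± 4.23 FPKM, and that list had a camera adjusted p = 0.0863, or 0.0168 without DCRT-KO replicate 1.

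**Figure D3:**
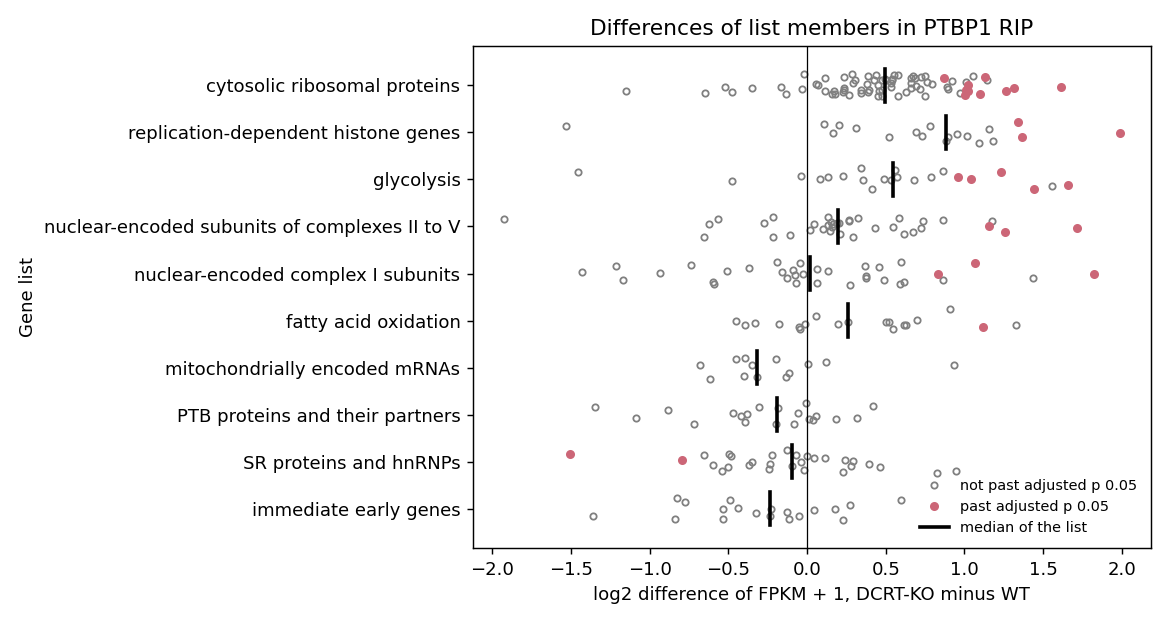
Log2 difference of FPKM + 1, DCRT-KO minus WT, of each tested member of 10 gene lists, with 1 point per gene (filled where the adjusted p was below 0.05) and a bar at the median of the list; the vertical scatter within a list has no meaning. The ribosomal protein, histone and glycolysis medians lie at 0.50, 0.88 and 0.55, and the medians of the mitochondrially encoded mRNAs, PTB proteins, SR proteins and hnRNPs, and immediate early genes lie below 0.

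None of 20 PTB proteins and partners passed, also when adjusted over the list alone, and 14 of them had lower values in DCRT-KO (mean log2 difference -0.28; camera adjusted p = 0.119, or 0.0238 with quantile normalization and 0.0296 with voom and quality weights). The partner KHSRP had 53.1 ± 1.11 FPKM in WT and 53.5 ± 10.6 in DCRT-KO. Of 26 tested transcripts known to be under PTBP1 control, 2 rose, the actin cross-linker FLNA among them, and none fell (4 and 3 adjusted over the list alone), with a median of -0.01, a mean of 0.07 and a camera adjusted p = 0.823 in the upward direction. FLNA rose from 75.9 ± 7.17 to 194 ± 81.1 FPKM (adjusted p = 0.0438). Among 29 SR proteins and hnRNPs, the splicing factor SRSF1 fell from 18.3 ± 3.10 to 6.01 ± 2.40 FPKM (adjusted p = 0.0274). SYNCRIP fell from 16.4 ± 0.704 to 9.06 ± 0.614 (adjusted p = 0.0423), and none rose. Adjusted over the list alone, 2 rose and 3 fell, and the list had a camera adjusted p = 0.449. Both genes lie in blocks of the genome, described below, where most genes were lower. Around SYNCRIP on chromosome 6, 31 of 33 genes, SYNCRIP included, were lower. Their median log2 difference of -0.79 is SYNCRIP's own value, so it is no separate comparison. Around SRSF1 on chromosome 17, 47 of 52, SRSF1 included, were lower, with a median of -0.44, against -1.51 for SRSF1. Whether these falls are separate from those of their neighbours was not tested.

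In the heart lists no gene passed with limma. Only 11 of 26 sarcomere and dilated cardiomyopathy genes and 7 of 12 cardiac stress genes reached the expression filter. The 11 tested sarcomere and dilated cardiomyopathy genes (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.449) included vinculin, VCL, at 84.2 ± 11.7 FPKM in WT and 77.4 ± 1.88 in DCRT-KO, and the co-chaperone BAG3 at 34.0 ± 1.63 and 47.7 ± 6.67. With voom, 2 of these 11 genes rose and 2 fell. FLNC rose from 19.0 ± 2.52 to 57.9 ± 34.3 FPKM (limma adjusted p = 0.0588, voom 0.00178). TPM1 fell from 13.3 ± 2.27 to 6.76 ± 0.955 FPKM (limma adjusted p = 0.0545, voom 0.00876). The 7 tested cardiac stress genes (none adjusted over the list alone; median 0.04, mean -0.19, camera downward, adjusted p = 0.597) included UCHL1 at 102 ± 20.4 and 96.0 ± 21.9 FPKM and FHL1 at 53.1 ± 4.89 and 55.6 ± 9.04.

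Among markers of other cell types, COL4A2, a basement membrane collagen, rose among 14 fibroblast and matrix genes (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0924, or 0.0176 without DCRT-KO replicate 3). The transcription factor ERG rose among 7 endothelial genes (3 adjusted over the list alone; median -0.18, mean 0.29, camera upward, adjusted p = 0.449). The keratin KRT18 rose among 4 epithelial genes, from 48.7 ± 2.27 to 143 ± 60.2 FPKM (1 adjusted over the list alone; camera adjusted p = 0.0863, or 0.0114 without DCRT-KO replicate 3). No blood or immune marker reached the expression filter, and the lists of long nuclear and of small structured noncoding RNAs were not analysed here.

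Stress and growth lists gave few calls. ISG15, an interferon-induced ubiquitin-like protein, rose from 3.52 ± 1.89 to 19.4 ± 9.31 FPKM (adjusted p = 0.0269), the only call among 8 type I interferon genes, also when adjusted over the list alone (median -0.08, mean 0.08, camera upward, adjusted p = 0.848). ISG15 rests on few reads, with 9, 9 and 3 in WT and 15, 5 and 18 in DCRT-KO. SLC7A11, the cystine transporter, fell from 14.2 ± 1.29 to 5.37 ± 1.76 FPKM (adjusted p = 0.0322), the only call among 19 stress response genes (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.532). MCM7, of the replicative helicase, rose from 23.0 ± 2.11 to 72.1 ± 20.98 FPKM (adjusted p = 0.0148) among 28 cell division genes (3 adjusted over the list alone; camera adjusted p = 0.386). None of 19 immediate early genes (none adjusted over the list alone; camera adjusted p = 0.119) and none of 20 p53 target genes (2 fell adjusted over the list alone; camera adjusted p = 0.449) passed. FOSL1 had 297 ± 13.5 FPKM in WT and 288 ± 33.7 in DCRT-KO, IER3 322 ± 49.6 and 296 ± 40.2, CDKN1A 78.6 ± 14.1 and 95.5 ± 24.8, and TNFRSF10B 60.9 ± 4.03 and 56.7 ± 12.6.

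The share of summed FPKM held by ribosomal protein genes was 4.83% ± 0.544 in DCRT-KO and 3.20% ± 0.225 in WT RIP (SD, n = 3 each), with no overlap between the groups (exact two-sided permutation p = 0.1, the smallest this design allows; 0.3 after adjustment over 3 shares). Mitochondrially encoded genes held 26.7% ± 6.53 and 32.7% ± 3.46, and the 10 highest genes 26.5% ± 5.91 and 32.4% ± 3.02, both with overlapping values (exact two-sided permutation p = 0.3). Mitochondrially encoded mRNAs are among the highest genes, so these shares overlap and are not separate results. In WT library a they were 29.92% and 30.03%.

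Across genes, which are not independent replicates, the log2 difference rose with the GC content of the transcript (Spearman 0.43), from a median of -0.34 in the lowest of 5 equal GC groups to 0.28 in the highest. Genes that rose had a median GC content of 57.7% and genes that fell 42.7%. Relative to the mean of all libraries, levels in WT libraries a, b and c fell with GC content (Spearman -0.27, -0.36 and -0.36). In DCRT-KO libraries 1, 2 and 3 they rose with it (0.23, 0.34 and 0.14). The GC trend and depth thus go with genotype. Loss of DCRT cannot be told apart here from other differences between the groups, such as library preparation. After each library's trend with GC content and length was removed, 167 genes passed, 154 of them among the 406. DCRT-KO library 3 lay nearer to the WT libraries (mean correlation 0.926) than libraries 1 and 2 did (0.86), and nearer to them than to libraries 1 and 2 (0.897). In libraries thinned to equal depth, its mean correlation was 0.868 both with WT and with libraries 1 and 2. The count of genes fell to 4, 8 and 0 without WT replicate a, b or c and to 204 and 65 without DCRT-KO replicate 1 or 2, and rose to 1528 without DCRT-KO replicate 3. Without DCRT-KO replicate 3 the balance reversed, with 707 genes higher and 821 lower, against 269 and 137 with all libraries; with voom it did not (859 higher, 527 lower). Without WT replicate c, limma had 1991 genes at an unadjusted p below 0.05 and called none, and voom on whole reads called 708. The 4 genes without WT replicate a were MYH13, MYH4, NTSR1 and ZFP57, the last 2 of them singled out after their values were seen.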

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

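The tests with voom, with thinned libraries, with the GC and length trend removed and without both shallowest libraries were chosen after the data were seen. Of the 48 named genes past the threshold, all kept their direction with median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, voom, the GC and length trend removed and thinned libraries. Under the other alternatives their direction could not change, because the groups of these genes do not overlap, so it says nothing about stability there. Many lost their call: 2, 5 and 0 of the 48 kept it without WT replicate a, b or c, 32, 16 and 48 without DCRT-KO replicate 1, 2 or 3, 24 without a variance trend and 24 without a filter, 28 with the GC and length trend removed, 21 in the first draw of thinned libraries, 9 without DCRT-KO replicates 1 and 2, and 41 with voom. The number of genes past the threshold did depend on the processing. Against 406 genes (269 higher, 137 lower), 122 (72, 50) passed without a filter, 134 (70, 64) without a variance trend, 167 (102, 65) with the GC and length trend removed, 38 (27, 11) without DCRT-KO replicates 1 and 2 and a median of 75 (53.5, 23) in thinned libraries. More passed with voom on whole reads, 1049 (659, 390), or with quality weights, 1294 (809, 485). A pseudocount of 0.1 left 90 lower genes, and quantile normalization gave 278. Leaving out 1 library gave between 0 and 1528 genes with limma (0 to 707 higher, 0 to 821 lower) and between 436 and 1386 with voom (299 to 859 higher, 137 to 527 lower). The excess of higher genes turned into an excess of lower ones with limma without DCRT-KO replicate 3 (707 higher, 821 lower). Fewer libraries leave fewer degrees of freedom, and thinning leaves fewer reads. The residual degrees of freedom are the same for each single library left out, so these alone do not account for counts from 0 to 1528. The degrees of freedom that limma adds from all genes were estimated anew in each fit and were not compared. The causes of these moves were not tested.

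For the lists, the ribosomal protein, histone and glycolysis lists lost their call only with an estimated correlation (adjusted p = 0.697 for each) and with fry (0.14 for each), which asks another question. Complexes II to V lost it in these (0.697 and 0.274) and, without DCRT-KO replicate 3 (0.000143 to 0.167 over libraries left out). Lists not past the threshold in the report passed as follows. PTB proteins and partners passed with quantile normalization (0.0238) and voom with quality weights (0.0296). Fatty acid oxidation passed without a filter (0.0117), with quantile normalization (0.0352) and without DCRT-KO replicate 1 (0.0168 to 0.207 over libraries left out). Mitochondrially encoded mRNAs passed without DCRT-KO replicate 1 (0.00332 to 0.937 over libraries left out), with voom (0.0268) and without DCRT-KO replicates 1 and 2 (0.00577). Fibroblast and matrix genes passed without DCRT-KO replicate 3 (0.0176 to 0.391 over libraries left out) and with voom and quality weights (0.0273). Epithelial markers passed without DCRT-KO replicate 3 (0.0114 to 0.223 over libraries left out), with voom and quality weights (0.0282) and in the first draw of thinned libraries (0.0255). Immediate early genes passed with quantile normalization (0.0244) and with the GC and length trend removed (0.00174). The cause was not tested.

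No paired analysis was possible because the WT columns carry no usable replicate numbers. The alternatives planned for transcript shares were not run, since each row of the table is a gene. Those planned for a table of raw counts were not run, since the table holds FPKM. The whole reads worked back from it were tested with voom instead. Depth limits low genes most: a single read is worth 2.68 RPM in DCRT-KO library 2 and 0.386 in WT library a.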

Other observations

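The tests of a mixture in DCRT-KO replicate 3 and the list of NF-kB target genes were chosen after the results were seen; the other tests in this part were set before their results. NF-kB is a transcription factor of inflammatory signalling. Of 23 tested NF-kB target genes, CXCL8, BIRC3, IL1B, CXCL1 and NFKBIA fell and none rose, 19 were lower in DCRT-KO PTBP1 RIP, and the median log2 difference was -0.56 (camera p = 3.28e-05, or p = 0.0843 with an estimated correlation). IL1B, interleukin 1 beta, fell from 129 ± 29.8 to 43.9 ± 12.3 FPKM (limma adjusted p = 0.0231), and NFKBIA, the NF-kB inhibitor, from 37.1 ± 7.63 to 15.7 ± 2.25 (adjusted p = 0.0267). ICAM1, an adhesion molecule also driven by NF-kB, had 5.19 ± 0.926 FPKM in WT and 10.1 ± 0.962 in DCRT-KO (adjusted p = 0.0588). The list holds CXCL8, CXCL1 and BIRC3, which prompted it, so its test is not independent evidence.

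Other genes had reads in every library of 1 group and none in the other. HDX on chromosome X had 35 reads in DCRT-KO and 0 in WT, and DPYSL4 on chromosome 10 had 16 and 0. EVC2, a ciliary protein on chromosome 4, had 70 reads in WT and 0 in DCRT-KO, and HSPA2, a heat shock protein on chromosome 14, had 36 and 0. CD274, which encodes the immune checkpoint ligand PD-L1, fell from 21.02 ± 1.75 to 4.41 ± 1.30 FPKM (limma adjusted p = 0.00829). The genes named in this paragraph were singled out after their values were seen.

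Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The genotype split gave 406 genes and the highest of the other splits 0 with limma, with 185 to 926 genes at an unadjusted p below 0.05 in the other splits against 2700.

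Log2 differences of neighbouring genes went together in blocks of the genome. Over 254 windows of 10 Mb with at least 15 genes, the SD of the median log2 difference was 0.246, against at most 0.128 in 1000 shuffles of gene positions. At 10 to 20 Mb of chromosome 12, 41 of 44 genes were lower in DCRT-KO, GPRC5D and TAS2R19 among them. In the first 10 Mb of chromosome 7, 50 of 56 genes were higher. The SD stayed above all shuffles with the GC and length trend removed (0.193 against 0.114), without neighbours of one gene family (0.24 against 0.131) and in the first draw of thinned libraries (0.258 against 0.142), which argues against each of these as the whole cause. Whether DNA copy number, regulation of whole domains or the knockout itself lies behind the blocks was not tested, for lack of DNA data.

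Ribosomal protein, glycolysis and histone genes were higher in DCRT-KO RIP, while the log2 difference followed GC content across all genes. With the GC and length trend removed, 3 of the 3 lists kept a camera adjusted p below 0.05, with medians of 0.43, 0.50 and 0.58 against 0.50, 0.55 and 0.88; in the first draw of thinned libraries 3 of the 3 also did. These calls use the preset correlation; with an estimated one each list has an adjusted p = 0.697 before any correction. At the preset correlation this argues against GC content, length and depth as the whole cause. Whether the rise of the chromosome 6 histone genes is separate from that of their block was not tested. Whether transcript abundance, PTBP1 binding or background RNA changed stays open without input or control antibody libraries.

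DCRT-KO replicate 3 lay nearer to WT than DCRT-KO replicates 1 and 2, which hold fewer reads. In libraries thinned to equal depth, 65.8% ± 2.0 (SD over 20 draws) of the gap in mean correlation remained, so depth accounts for part of it at most. WT RNA mixed into replicate 3 would bring at least its own share of every transcript that replicates 1 and 2 lack. Over 18 such genes the level in replicate 3 ran from 0% of WT in ZNF850, STOM and EVC2 to 133% in SPAG1. One share in every gene does not describe these values (chi-square per degree of freedom 6.38, against at most 2.69 between the other libraries for genes with 10 to 230 reads; Monte Carlo p = 0.00257 with that spread). Replicate 3 may have its own level of these genes on top of a share, however, so only genes below the share count against a mixture. Reads of replicate 1 or 2 mixed with those of a WT library matched replicate 3 at 37.6% of WT reads on average and 33.3% in the lowest of 6 mixes. At 33.3%, 2 of the 18 genes lay below the 5% lower limit, where up to 3 would be expected by chance if every gene could reach it. Genes with few expected reads could not, since EVC2 stayed above the limit with 0 reads against 4.99 expected. The count therefore cannot decide on a mixture. ZNF850, the gene with most WT reads, was 1 of the 2 below it, with 0 reads against 16.4 expected. Taken alone, ZNF850 would allow a share of at most 10.4%, which gives 33.2% of the gap. A mixture would also dilute genes with no read in WT, unless replicate 3 had more of them itself. The 5 myosins had 196 RPM in replicate 3 and 136 in replicates 1 and 2 together, and 3 other genes 16.7 and 43.3 RPM. ZNF850 thus goes against a mixture of the size needed, but it is 1 gene and the count over the set cannot decide, so a mixture stays open. A difference between cultures or between immunoprecipitations was not tested.

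PTBP1 binds CU-rich sequence, so a change in binding alone might follow the density of CU-rich tetramers in the transcript. Across 11437 genes the log2 difference fell with that density (Spearman -0.31), but it also followed GC content (0.43). Given GC content and length, the partial correlation was -0.13, above the size of 0.1 set beforehand. Slightly lower recovery of CU-rich transcripts in DCRT-KO is a hypothesis that would give such a value. Other tetramers of like composition were not tested, so the value is not shown to be specific to CU-rich sequence. A GC trend that ranks do not capture also stays open.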
